A study of Homo sapiens with 24 samples.

How the data were processed

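Total RNA was extracted from 12 formalin-fixed, paraffin-embedded tumors, separately for 1 low-grade and 1 high-grade area of each, and made into stranded total RNA libraries, per the labels' protocols. The areas were outlined on a stained section and scraped from unstained sections under a stereomicroscope, per the labels' protocols, so an area is a mixture of tumor, stromal, vascular and immune cells. Formalin-fixed RNA is fragmented, which lowers and unevens coverage of transcripts. STAR 2.7.0a, edgeR 3.34.0 and the genome build hg19 are named in the submitters' processing notes. The counting program, the gene annotation and the strand setting are not given in the sources used here, so reads of overlapping, antisense or near-identical genes cannot be assigned with certainty.

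The authors deposited 2 tables. The first holds raw counts for 33573 gene symbols in 24 libraries, and the deposited counts are whole numbers whose totals differ between libraries. The second holds log2 CPM values scaled by TMM factors for 19842 of those symbols, per the file headers. The deposited log2 values equal log2 CPM computed with edgeR (TMM over the 19842 symbols, prior count of 2) to within 0.000500. Among those symbols, 63 each stand for more than 1 gene identifier (up to 4), per the file headers. Genes are named by the symbols in the tables. No coordinates are given, because the reference annotation at hand belongs to another genome build than hg19.

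Libraries were grouped by the area label, and the number in each title ties the areas of one tumor together. The tumors were renumbered from 1 to 12. As areas of one tumor share a donor, the tumor was a block in the model. The deviations of the areas of a tumor from their group means correlated at -0.00561 in tumor 3, whose low-grade library was the shallowest, and positively in the others. A comparison of 6 sex-linked genes between the areas of each tumor found 0 discordant tumors, and 0 pairs of libraries were identical. Genes of chromosome Y and XIST are not reported.

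Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Low counts were removed with filterByExpr at its defaults, which left 23620 symbols tested and 9953 not tested. TMM factors, robust dispersions and the quasi-likelihood F test (glmQLFit and glmQLFTest) were used, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are high-grade over low-grade, and the SE of a log2 fold change is its size divided by the square root of F. Levels are mean CPM ± SD over 12 areas, scaled by the TMM factors. Total counts set the precision: a gene at 1 CPM has about 3 counts in the shallowest library. For the blocked gene test and the sign-flip tests, p-values measure the spread between tumors, 1 area of each kind per tumor. They rest on 12 tumors unless 1 is left out. The p-values of camera, a list test described below, compare the genes of a list with the other genes. At its preset correlation, genes of a list count as nearly independent.

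Before the data were examined, 37 gene lists were fixed from general knowledge of cell types and pathways. They cover the cell cycle, chromatin, metabolism, signaling and stress, and the neural, stromal, vascular and immune cell types that an area could hold. Symbols were matched to older names where needed. For each list, the mean difference in log2 CPM (prior count of 2) between the areas of a tumor was tested over the 12 tumors with an exact two-sided sign-flip permutation test of all 4096 sign patterns, adjusted over the lists. Camera at a preset correlation of 0.01, camera with an estimated correlation, and fry were run beside it. Members of a list were counted over all genes tested and adjusted over the list alone. Relations across tumors used 100000 permutations.

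The genes named in the text follow a rule fixed before the data were examined. The first part takes up to 12 genes in each direction with the largest change among those past the threshold, with a mean of at least 1 CPM and the same direction in at least 10 of 12 tumors. It leaves out immunoglobulin and T cell receptor segments and loci without a gene name. The second part takes the up to 4 members with the smallest p of each list described, and the third part 7 fixed genes: MKI67, TOP2A, COL1A1, GFAP, SNAP25, CDKN2A and BRAF.

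Alternatives chosen before the data were examined were a model without the block, DESeq2 1.42.0, limma-voom, limma on the authors' log2 values, DESeq2 size factors, upper-quartile factors, no filter on low counts, a filter of 5 CPM in 12 libraries, library size as a covariate, a fold threshold of 1.5, and each tumor left out in turn. For the lists, they were estimated correlation, fry, no block, upper-quartile factors, the stricter filter, the authors' log2 values, the median over members and each tumor left out. After seeing the data, library quality weights, offsets for GC content and length, a covariate for the desmoplastic matrix list, the authors' symbols alone, other scaling factors for list scores, and library size for the lists were added. The procedure was tested on simulated counts for the comparison of high-grade against low-grade areas, over 23620 genes of which 50 were changed at each fold. It recovered 46% of genes changed by 1.5-fold, 88% by 2-fold, 92% by 3-fold and 96% by 4-fold, with 8 false among 173 calls (4.62%). Genes changed at each fold had a mean above 1 CPM, and the endothelium list was shifted as well. Counts were drawn independently for each gene, with the same change in every tumor. These shares therefore do not cover correlated genes or changes that vary between tumors.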

Results

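The data were RNA sequencing profiles of microdissected areas of desmoplastic infantile astrocytoma and ganglioglioma, rare brain tumors made of astrocytic and, in the ganglioglioma, neuronal cells within a collagen-rich (desmoplastic) stroma. Each of 12 formalin-fixed, paraffin-embedded tumors gave 1 area of low-grade and 1 area of high-grade appearance, both marked on stained sections and scraped off, so that there were 12 low-grade and 12 high-grade libraries. The comparison asks which transcripts differ between the high-grade and the low-grade area of the same tumor, and n is the number of tumors throughout. The areas were picked by their appearance on stained sections, and the features used to grade them are not given in the sources used here. The tumors are numbered 1 to 12 here. The total count per library ranged from 2346374 to 76300225, with a median of 33.0 M counts. The lowest total belonged to the low-grade area of tumor 3, in which 11.2% of the counts lay in mitochondrially encoded genes, against at most 1.93% in any other library. The plot of depth and mitochondrial share shows this library apart from the rest. Depth did not differ detectably between the areas (medians 33.0 M in low-grade and 32.8 M in high-grade areas, mean difference 0.448 M, higher in 7 of 12 tumors, exact two-sided sign-flip permutation p = 0.921).

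**Figure D1:**
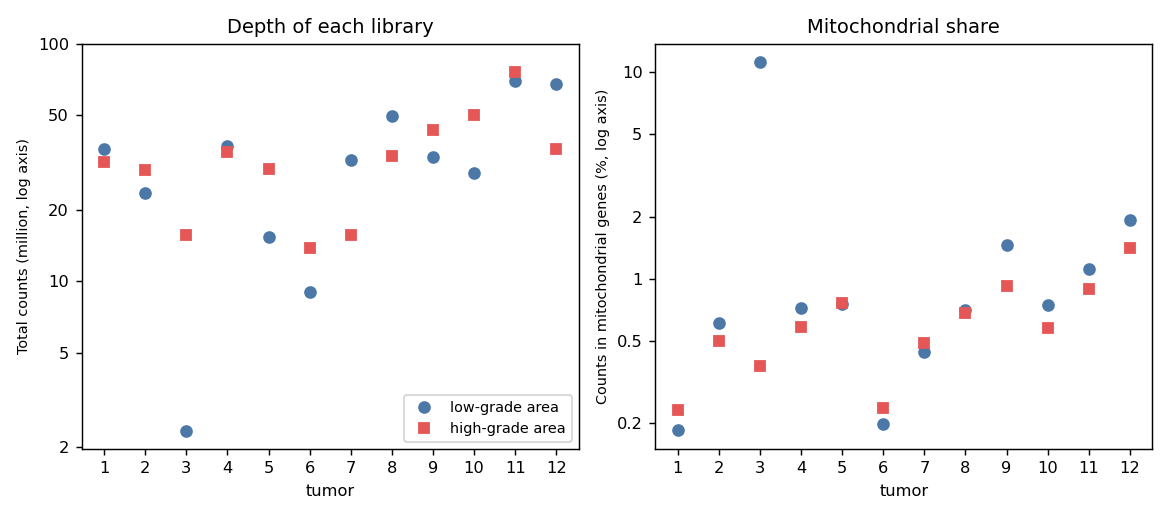
Total counts in M (left, log axis) and the percent of counts in mitochondrially encoded genes (right, log axis) against tumor number, with circles for the low-grade and squares for the high-grade area of each of the 12 tumors. The low-grade area of tumor 3 lies lowest on the left at 2.35 M and highest on the right at 11.2%.

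The areas of a tumor resembled each other more than they resembled libraries of other tumors. Across the 23620 genes tested, the median Pearson correlation of log2 CPM was 0.961 between the areas of one tumor and 0.918 between libraries of different tumors. Of the 24 libraries, 21 correlated best with the other area of their own tumor. These correlations are across genes, which are not independent replicates. For the median gene, the tumor accounted for 70.9% of the variance of log2 CPM, where 47.8% would be expected on average with no effect. The area accounted for 2.7%, and 4.35% is the mean expected with no effect of tumor or area. A median beside that mean, with most variance taken by the tumor, cannot show whether the area's share differs from chance. In tumor 3 the areas correlated at 0.721, the lowest value of the 12 tumors.

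The genes that were higher in high-grade areas included ones known for roles in cell division, cell adhesion and chromatin regulation. ASPM, a spindle pole protein of dividing cells, was at 14.7 ± 10.2 CPM in low-grade and 27.2 ± 14.2 CPM in high-grade areas (mean ± SD, n = 12), a log2 fold change of 0.92 ± 0.14 (SE). CCNB2, a mitotic cyclin, went from 10.1 ± 3.21 to 18.2 ± 8.48 CPM (log2 fold change 0.81 ± 0.14). EZH2, the methyltransferase of Polycomb repressive complex 2, rose from 17.0 ± 3.80 to 25.4 ± 9.19 CPM (0.55 ± 0.10) and was higher in 12 of 12 tumors. CDH2, which encodes N-cadherin, rose from 195 ± 77.3 to 342 ± 157 CPM (0.83 ± 0.15). The neuroligins NLGN4X (0.89 ± 0.16) and NLGN1 (0.73 ± 0.13), synaptic adhesion proteins, were, like CDH2, higher in 12 of 12 tumors. The largest increase among genes past the threshold was in AJAP1, which encodes a protein of adherens junctions, from 66.2 ± 49.0 to 215 ± 243 CPM (log2 fold change 1.47 ± 0.23, higher in 11 of 12 tumors).

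The genes that were lower in high-grade areas included several known from myeloid and other immune cells. LILRB2, an inhibitory receptor of myeloid cells, fell from 8.72 ± 5.47 CPM in low-grade to 4.61 ± 3.26 CPM in high-grade areas (log2 fold change -1.01 ± 0.19). C5AR1, the receptor for the complement fragment C5a, changed by a log2 fold change of -0.67 ± 0.10 from 35.8 ± 27.2 CPM in low-grade areas, and both were lower in 12 of 12 tumors. PTGER4, a prostaglandin E2 receptor (-0.75 ± 0.12), FGD2 (-0.71 ± 0.12), SLA, an adaptor protein of antigen receptor signaling (-0.57 ± 0.09), FLI1, a transcription factor of blood and endothelial cells (-0.53 ± 0.10), and the interferon-induced XAF1 (-0.69 ± 0.12) fell as well. Among the genes past the threshold, HOXB4, a homeobox gene, had the largest decrease, from 2.48 ± 1.51 to 0.886 ± 0.556 CPM (-1.43 ± 0.24, lower in 12 of 12 tumors). STEAP4, a metalloreductase, fell from 28.1 ± 22.1 to 14.8 ± 14.1 CPM.

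In edgeR's quasi-likelihood test with the tumor as a block, 14 genes were higher and 15 lower in high-grade areas at a Benjamini-Hochberg adjusted p under 0.05 among 23620 genes. Of these, 3 and 4 changed by at least 2-fold. Besides those above, HIST1H3C (1.43 ± 0.26), MEX3A (1.14 ± 0.17), MPPED2 (0.92 ± 0.17), TMEM200C (0.87 ± 0.13) and VANGL2 (0.53 ± 0.09) were higher. Likewise, HCG27 (-0.69 ± 0.13), TNFAIP2 (-0.65 ± 0.10) and STARD8 (-0.60 ± 0.11) were lower. The adjusted p of the 24 named genes lay between 0.0256 for C5AR1, MEX3A and TMEM200C and 0.0488 for HIST1H3C and some others, so that each call was close to the threshold. At an unadjusted p under 0.05, 1718 genes were higher and 2100 lower. Both counts were 0 when the tumor was left out of the model, where edgeR gave 553 higher and 994 lower at an unadjusted p under 0.05. With the block, limma-voom called 92 and 148 genes and DESeq2 called 563 and 897. Both counts also became 0 when any of tumors 1, 2, 4, 5, 7, 8 or 9 was left out, were 24 and 23 without tumor 3, and were 71 and 122 without tumor 6.

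**Figure D2:**
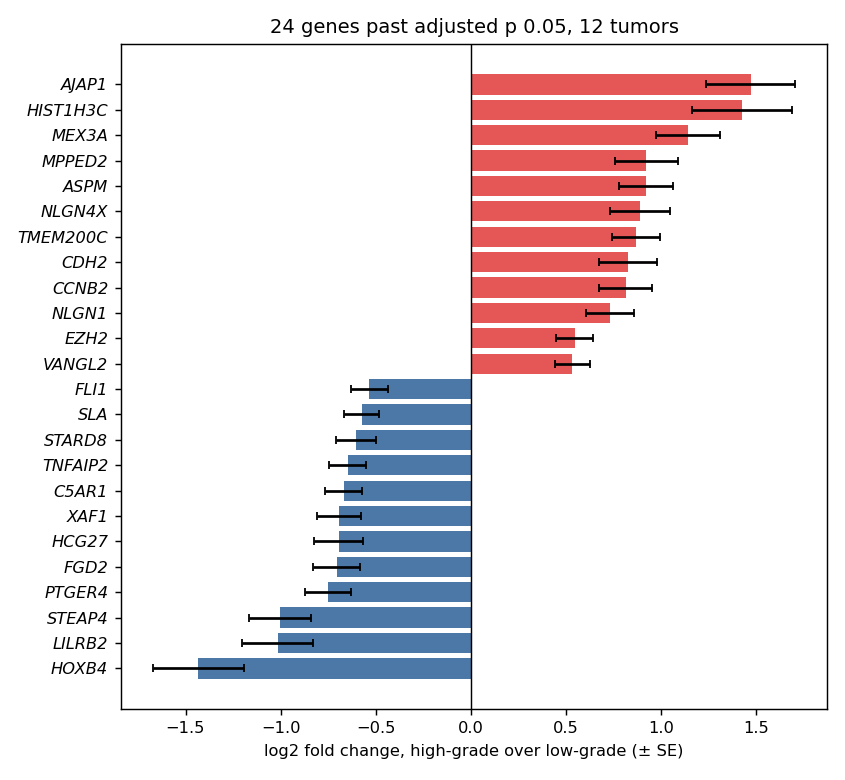
Log2 fold change of high-grade over low-grade areas (horizontal axis; bars from 0, error bars ± SE of the edgeR model with the tumor as a block, n = 12 tumors) for the 24 genes with the largest changes among those past the threshold. Values run from -1.43 for HOXB4 to 1.47 for AJAP1.

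Genes of the cell cycle were measured with 3 lists. Of 14 replication-dependent histone genes, which are transcribed in S phase, all 14 had a positive log2 fold change. Adjusted over the list alone, 9 were higher, and 1, HIST1H3C, over all genes tested. Examples are HIST1H2BM (1.04 ± 0.24, from 0.760 to 1.89 CPM), HIST1H1B (1.01 ± 0.24, from 3.30 to 6.69 CPM) and HIST1H2BH (0.93 ± 0.25, from 1.41 to 2.79 CPM). Histone genes are close copies of one another, so reads may be divided between them, and the levels of single members are uncertain. The mean change of the list per tumor was 0.83 ± 0.63 on the log2 scale (SD, n = 12). It was positive in 11 of 12 tumors, and the list rose (exact two-sided sign-flip permutation test, adjusted p = 0.0120). With camera the list was called at its preset correlation, but the adjusted p = 0.164 with an estimated correlation.

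Of 30 genes of G2 phase and mitosis, 28 had a positive log2 fold change, 12 were higher when adjusted over the list alone and 2, ASPM and CCNB2, over all genes tested. TOP2A, a topoisomerase of dividing cells, had a log2 fold change of 0.96 ± 0.21 (from 9.34 ± 5.25 to 20.9 ± 19.4 CPM, edgeR adjusted p = 0.0678, higher in 11 of 12 tumors). The proliferation marker MKI67 had one of 0.68 ± 0.21 (from 20.2 ± 12.8 to 37.7 ± 40.0 CPM, edgeR adjusted p = 0.145, higher in 9 of 12 tumors). NUSAP1 (0.57 ± 0.16) was higher in 12 of 12 tumors. The list's mean change was 0.48 ± 0.62 and positive in 10 of 12 tumors, which missed the threshold after adjustment (exact sign-flip p = 0.0151, adjusted p = 0.0622). Its call by camera was lost with an estimated correlation (adjusted p = 0.342). Leaving out 1 tumor, the list passed without tumor 3 (mean change 0.58, positive in 10 of 11 tumors, exact sign-flip adjusted p = 0.0161) and without tumor 1 (0.55, adjusted p = 0.0465). It did not pass without any of the other 10, with 0.35 without tumor 5 (adjusted p = 0.0994) and the highest adjusted p, 0.116, without tumor 11. With the median over members in place of the mean it passed as well (0.51, adjusted p = 0.0361). Of 30 genes of G1/S and DNA replication, 23 were positive and 1, the replicative helicase subunit MCM7 (0.37 ± 0.10), was higher when adjusted over the list alone, with none over all genes tested. That list's mean change of 0.12 ± 0.42, positive in 11 of 12 tumors, did not pass (adjusted p = 0.539). It was 0.22 without tumor 3, positive in 11 of 11 tumors (adjusted p = 0.00903), and 0.05 without tumor 5 (adjusted p = 0.831). The list of DNA damage response and homologous recombination went from 0.15 ± 0.39 (adjusted p = 0.383) to 0.23 without tumor 3 (positive in 11 of 11 tumors, adjusted p = 0.00903) and to 0.07 without tumor 5 (adjusted p = 0.653). Neither of these lists passed with any tumor other than tumor 3 left out.

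The list of Polycomb and DNA methylation machinery rose in 12 of 12 tumors, by a mean of 0.24 ± 0.14 on the log2 scale (SD; exact sign-flip test, adjusted p = 0.00903; camera adjusted p = 0.127 with an estimated correlation). All 13 members were positive, 6 were higher when adjusted over the list alone, and 1, EZH2, over all genes tested. TET1, a methylcytosine dioxygenase, had a log2 fold change of 0.58 ± 0.14 (79.9 to 121 CPM). JARID2, a subunit of Polycomb repressive complex 2, had one of 0.32 ± 0.09 (65.4 to 83.5 CPM) and CBX2, a subunit of Polycomb repressive complex 1, one of 0.57 ± 0.16 (7.12 to 11.0 CPM). Nuclear genes of the mitochondrial respiratory chain rose by a mean of 0.16 ± 0.20 in 10 of 12 tumors (adjusted p = 0.0439; camera adjusted p = 0.431 with an estimated correlation). Of these 14 genes 12 were positive, and 1, UQCRFS1 (0.29 ± 0.08), was higher when adjusted over the list alone, with none over all genes tested. This list no longer passed when any of tumors 1, 2, 3, 5, 6, 9 or 11 was left out, with an adjusted p between 0.0558 without tumor 3 and 0.0878 without tumor 5.

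Lists of immune cells other than granulocytes and mast cells fell in high-grade areas. The list of granulocytes and mast cells did not pass (-0.18 ± 0.43, lower in 8 of 12 tumors, adjusted p = 0.301; -0.08 without tumor 3). The T cell list fell in 12 of 12 tumors, with a mean change of -0.75 ± 0.55 (SD; exact sign-flip test, adjusted p = 0.00903; camera adjusted p = 0.127 with an estimated correlation). Of its 10 measured members, 8 were lower when adjusted over the list alone and none over all genes tested. Examples are IL7R (-0.88 ± 0.20, 7.81 to 4.28 CPM), CD4, which macrophages also express (-0.50 ± 0.15, 61.8 to 44.0 CPM), and ZAP70 (-0.47 ± 0.15, 3.73 to 2.59 CPM). The list of microglia and macrophages fell in 11 of 12 tumors, with a mean change of -0.38 ± 0.30 (adjusted p = 0.0120; camera adjusted p = 0.190 with an estimated correlation). Of its 17 measured members, 9 were lower when adjusted over the list alone and none over all genes tested. Among them were the scavenger receptor CD163 (-0.70 ± 0.14, 445 to 284 CPM, lower in 12 of 12 tumors), MS4A4A (-0.69 ± 0.14) and CSF1R, the receptor for the myeloid growth factor CSF1 (-0.43 ± 0.11, 240 to 183 CPM).

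All 9 genes of antigen presentation by MHC class II were lower when adjusted over the list alone, and none over all genes tested. The list fell, with a mean change of -0.53 ± 0.44, in 10 of 12 tumors (adjusted p = 0.0120; camera adjusted p = 0.190 with an estimated correlation). Its members included CIITA, the transactivator of the class (-0.58 ± 0.13, 193 to 128 CPM, lower in 12 of 12 tumors), and HLA-DMA (-0.61 ± 0.14). The HLA genes are similar to one another and vary between people, so reads may be shared or lost between them. The interferon response list fell in 11 of 12 tumors, with a mean change of -0.41 ± 0.35 (adjusted p = 0.0120; camera adjusted p = 0.190 with an estimated correlation). Of its 16 members, 11 were lower when adjusted over the list alone and none over all genes tested. MX2 (-0.94 ± 0.19, 43.1 to 21.9 CPM), MX1 (-0.57 ± 0.11) and OAS2 (-0.48 ± 0.11), antiviral proteins, were among them. The list of B and plasma cells fell in 9 of 12 tumors, with a mean change of -0.62 ± 0.97 (adjusted p = 0.0452; camera adjusted p = 0.342 with an estimated correlation). However, none of its 7 measured members passed even when adjusted over the list alone. This list passed only without tumor 4, 6 or 12 when 1 tumor was left out, and was at -0.39 without tumor 3 (adjusted p = 0.0602). It also missed the threshold with the median over members (-0.60, adjusted p = 0.0761) and with 2 other kinds of size factor (adjusted p = 0.0542 for both).

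**Figure D3:**
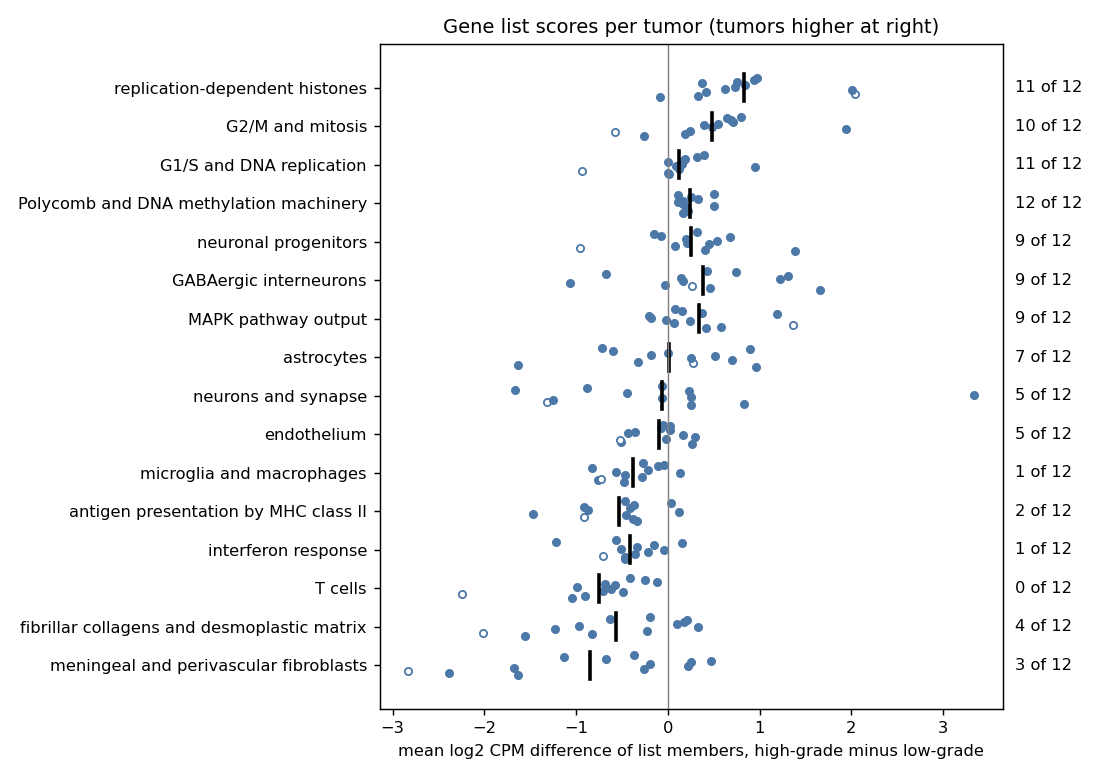
Mean log2 CPM difference between the high-grade and the low-grade area over the members of 16 gene lists (horizontal axis), with 1 point per tumor (open for tumor 3), a black line at the mean of the 12 tumors, and the number of tumors with a higher value at the right. The T cell points lie below 0 in 12 of 12 tumors and those of the Polycomb list above 0 in 12 of 12, while the points for neurons and synapse lie on both sides of 0, above it in 5 of 12.

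Stromal lists were lower on average in high-grade areas but varied between tumors. Of 14 genes of meningeal and perivascular fibroblasts, all 14 had a negative log2 fold change and 8 were lower when adjusted over the list alone, with none over all genes tested. Examples are FOXC1 (-0.84 ± 0.23), CLDN11 (-0.92 ± 0.29) and OGN (-0.84 ± 0.29). Of 20 genes of fibrillar collagens and desmoplastic matrix, 19 were negative and 5 were lower when adjusted over the list alone, with none over all genes tested. They include the fibroblast activation protein gene FAP (-0.89 ± 0.23) and decorin, DCN (-0.94 ± 0.29, 732 to 422 CPM). COL1A1, a chain of type I collagen, was at 5246 ± 4726 CPM in low-grade and 3030 ± 2891 CPM in high-grade areas (-0.97 ± 0.51, edgeR adjusted p = 0.362, lower in 9 of 12 tumors). Neither list passed the sign-flip test. The fibroblast list had a mean change of -0.85 ± 1.08, lower in 9 of 12 tumors (adjusted p = 0.0706), and the matrix list one of -0.57 ± 0.76, lower in 8 of 12 tumors (adjusted p = 0.0723). Both were called by camera, with an adjusted p = 0.342 with an estimated correlation.

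With all 12 tumors and the mean over members, lists of neural cell types gave no change in either direction that passed. The astrocyte list had a mean change of 0.01 ± 0.76 (adjusted p = 0.958) and the list of neurons and synapse one of -0.07 ± 1.32 (adjusted p = 0.930). With 1 tumor left out they ranged from -0.07 to 0.16 and from -0.38 to 0.08. Camera called the lists of GABAergic interneurons (mean change 0.38 ± 0.79, higher in 9 of 12 tumors), radial glia and neural stem cells (0.20 ± 0.52, higher in 8 of 12) and myelinating oligodendrocytes (-0.45 ± 0.76, lower in 10 of 12). Their sign-flip adjusted p was 0.259, 0.365 and 0.102, and with an estimated correlation the adjusted p = 0.431, 0.437 and 0.431. The oligodendrocyte list was at -0.30 without tumor 9 (adjusted p = 0.192) and passed without tumor 7 (-0.53, adjusted p = 0.0258), and the radial glia list was at 0.12 without tumor 1 (adjusted p = 0.515) and at 0.30 with the median over members (adjusted p = 0.0913). The interneuron list was at 0.27 without tumor 1 (adjusted p = 0.437), at 0.56 in the authors' deposited values (adjusted p = 0.121) and at 0.66 with the median over members (adjusted p = 0.0840). Oligodendrocyte precursors (0.14 ± 0.67, adjusted p = 0.586) and ependyma and cilia (-0.18 ± 0.72, adjusted p = 0.583) did not pass either. Single tumors set most of these means, which were 0.03 without tumor 5 and -0.04 without tumor 2. GFAP, the astrocyte intermediate filament, had a log2 fold change of -0.40 ± 0.31 (edgeR adjusted p = 0.544), and SNAP25, a neuronal synaptic protein, one of 0.36 ± 0.38 (edgeR adjusted p = 0.664). The neuronal progenitor list had a mean change of 0.25 ± 0.55 in 9 of 12 tumors (adjusted p = 0.294). Camera called this list too, but the adjusted p = 0.342 with an estimated correlation. Of its 11 members, 6 were higher and 1 was lower when adjusted over the list alone and none over all genes tested. SOX11 (1.12 ± 0.21, 69.5 to 133 CPM), DCX (1.23 ± 0.34, 46.8 to 93.5 CPM), both expressed by immature neurons, and STMN1 (0.61 ± 0.20) were positive. EOMES was the member that was lower (-1.44 ± 0.56, 1.40 to 0.411 CPM; chosen after its value was seen). Without tumor 3 the list passed (0.36, 9 of 11 tumors, adjusted p = 0.0325). It did not pass with any other tumor left out, and was 0.15 without tumor 1 (adjusted p = 0.447). It passed in the authors' deposited log2 values (0.74, adjusted p = 0.00854) and with the median over members (0.48, adjusted p = 0.0294). The deposited values cover fewer symbols, so fewer members of this list and of the interneuron list may have been scored there. Lists of endothelium (-0.10 ± 0.29, adjusted p = 0.388) and of erythroid cells and platelets (-0.16 ± 0.73, adjusted p = 0.627) did not pass. Those of pericytes and smooth muscle (-0.23 ± 0.39, adjusted p = 0.152; camera called it, but the adjusted p = 0.431 with an estimated correlation), basement membrane (-0.20 ± 0.45, adjusted p = 0.295) and Schwann cells (-0.10 ± 0.48, adjusted p = 0.586) did not pass either. Without tumor 3 the means were -0.06 for endothelium, 0.01 for erythroid cells and platelets, -0.17 for pericytes and -0.04 for Schwann cells, and without tumor 2 that of basement membrane was -0.13.

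Genes of the MAPK pathway, which is often activated in these tumor types, were measured through its transcriptional output. The list had a mean change of 0.34 ± 0.50, higher in 9 of 12 tumors, and did not pass (adjusted p = 0.0723; camera called it, but the adjusted p = 0.431 with an estimated correlation). Leaving out 1 tumor, it passed without tumor 7 alone (0.38, adjusted p = 0.0470). Of its 18 members, 8 were higher and 1 lower when adjusted over the list alone and none over all genes tested. Examples are SPRY4 (0.83 ± 0.21, 444 to 737 CPM), EPHA2 (0.55 ± 0.14) and ETV4 (0.58 ± 0.16). The list of 24 measured glioma driver genes and growth factor receptors did not pass, with a mean change of -0.02 ± 0.17, higher in 6 of 12 tumors (adjusted p = 0.748). The mean of its fitted log2 fold changes was -0.01, the median 0.08. Adjusted over the list alone, 2 members were higher, among them the cell cycle kinase gene CDK6 (0.55 ± 0.13, 154 to 226 CPM), and 1, EGFR (-0.69 ± 0.18), was lower, with none over all genes tested. BRAF had a log2 fold change of 0.16 ± 0.09 (edgeR adjusted p = 0.402) and CDKN2A, a cell cycle inhibitor, one of 0.07 ± 0.12 (edgeR adjusted p = 0.816). The 13 mitochondrially encoded genes were all negative, with a mean change of -0.60 ± 1.30, lower in 9 of 12 tumors (adjusted p = 0.0706), of which tumor 3 alone had -4.60. Camera called this list, with an adjusted p = 0.516 with an estimated correlation. It passed the sign-flip test without tumor 6 (-0.68, adjusted p = 0.0452) and without tumor 7 (-0.67, adjusted p = 0.0470), and was at -0.24 without tumor 3 (adjusted p = 0.111). All 18 cytosolic ribosomal protein genes were positive, with a mean change of 0.18 ± 0.27 that did not pass (adjusted p = 0.101; camera called it, but the adjusted p = 0.431 with an estimated correlation) except without tumor 1 (0.22, adjusted p = 0.0497). Lists of hypoxia (0.06 ± 0.44), glycolysis (0.13 ± 0.44), heat shock and unfolded protein stress (-0.11 ± 0.48) and immediate-early genes (-0.12 ± 0.70) did not pass, nor did the list of mesenchymal transition (-0.14 ± 0.31). Without tumor 5 the hypoxia list was at -0.07 and glycolysis at 0.02, without tumor 3 heat shock was at -0.03, and without tumor 8 immediate-early genes were at 0.01. The mesenchymal list was at -0.09 without tumor 7 and at -0.20 with the median over members (adjusted p = 0.0840).

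Of 37 lists, 3 rose and 5 fell in the sign-flip test over the 12 tumors, whose smallest possible p is 0.000488. Fry, which tests whether a list's members move on balance in 1 direction, called 6: Polycomb (adjusted p = 0.00171), T cells (0.00304), histones (0.00777), microglia and macrophages (0.0105), MHC class II (0.0108) and interferon response (0.0141). Camera at a preset correlation of 0.01 called 9 lists as higher and 10 as lower, and 0 of these held with an estimated correlation, where 6 lists had an unadjusted p under 0.05.

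The change of the mitosis list across tumors was compared with that of 5 other lists. No relation passed after adjustment over the 5 with all 12 tumors. With 1 tumor left out, r varied widely. The matrix list ranged from 0.0395 to 0.860, highest without tumor 5 (permutation p = 0.0013). Endothelium ranged from 0.262 to 0.742, highest without tumor 1 (permutation p = 0.0023). These p-values belong to the highest r of each list and are adjusted neither for that choice nor over the 5 relations, so they decide nothing. Over all 12 tumors the largest r was with endothelium (Pearson r = 0.481, permutation p = 0.111, adjusted p = 0.555; Spearman rho = 0.434, p = 0.161, adjusted p = 0.402). Without the 2 tumors farthest from the median of the mitosis change, tumors 3 and 5, r was -0.112. With the desmoplastic matrix list r was 0.351 (permutation p = 0.269, adjusted p = 0.673; rho = 0.469, p = 0.126, adjusted p = 0.402), and 0.746 without those 2 tumors. Values of r were 0.234 for microglia and macrophages (p = 0.476, adjusted p = 0.794; rho = 0.301, p = 0.340). They were 0.0631 for astrocytes (p = 0.841, adjusted p = 0.878; rho = -0.119, p = 0.714) and 0.0441 for neurons (p = 0.878, adjusted p = 0.878; rho = -0.119, p = 0.718).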

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

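The tests with quality weights, GC and length offsets, the matrix covariate, the authors' symbols, library size for the lists and other scaling of list scores were chosen after the results were seen, as were all those on gene families. All 619 alternative values of the 24 named genes past the threshold kept their direction, and 299 kept the call. The counts of genes higher and lower (14 and 15) were 0 and 0 without the replicate block, 563 and 897 with DESeq2, 92 and 148 with limma-voom, and 36 and 49 with limma on the deposited log2 values. They were 59 and 110 with the stricter filter, 246 and 318 with quality weights, 33 and 48 on the authors' symbols, and 0 and 0 at a fold threshold of 1.5 and with the matrix covariate. GC and length offsets gave 29 and 31, but only 76% of the tested genes had a value, so that check cannot speak for the other genes. Of the 29 main calls, 27 were tested there and 26 passed again in the same direction. In edgeR at an unadjusted p under 0.05, the counts of 0 stand beside 553 and 994 without the block, 122 and 269 at the fold threshold and 486 and 632 with the matrix covariate. Library size as a covariate gave 11 and 11, with 15 of the 29 calls kept and all 29 in the same direction. Leaving out 1 tumor gave 0 to 71 genes higher and 0 to 122 lower. Both counts were 0 without tumor 1, 2, 4, 5, 7, 8 or 9. They were 2 and 2 without tumor 10, 5 and 6 without tumor 11, and 0 and 2 without tumor 12. Fewer tumors or genes entered some of these fits, and otherwise the cause was not tested. Lists called by camera (9 higher, 10 lower) were 0 and 0 with an estimated correlation, 2 and 4 with fry, and 9 and 6 with the matrix covariate. With 1 tumor left out, camera called 7 to 11 higher and 9 to 12 lower. By sign-flip test (3 higher, 5 lower), the median over members gave 5 higher, and leaving out 1 tumor gave 2 to 6 higher and 4 to 6 lower. The B and plasma cell list kept its direction but missed the threshold in 12 of 15 alternatives, and the respiratory chain list in 7 of 16. The other 6 lists that passed did so in all 16. The gap between the median correlations within and between tumors (0.0430) was 0.333 over the 1000 most variable genes. Some values that had not passed a test changed sign. CDKN2A was at -0.101 with quality weights, -0.0549 with the matrix covariate and -0.0103 to 0.117 with 1 tumor left out. SNAP25 was at -0.131 with quality weights and -0.154 with the matrix covariate, and COL1A1 at 0.0760 with the latter. With the matrix covariate the mean log2 change was 0.0256 for basement membrane, -0.201 for astrocytes, -0.122 for oligodendrocyte precursors and -0.0789 for hypoxia. It was -0.0316 for glycolysis, 0.0463 for erythroid cells and platelets and 0.145 for Schwann cells. Astrocytes also turned with upper-quartile factors (-0.0234), the stricter filter (-0.0386), library size (-0.00499) and the deposited values (-0.00901). Neurons turned with the stricter filter (0.00687) and library size (0.111), and the glioma driver list with the median over members (0.115). With 1 tumor left out, the fitted mean of the neuron list ranged from -0.373 to 0.0792 and its score from -0.376 to 0.0787. For astrocytes they ranged from -0.0736 to 0.155 and from -0.0742 to 0.161, and for hypoxia from -0.0705 to 0.0870 and from -0.0676 to 0.0877. For immediate-early genes they ranged from -0.197 to 0.00543 and from -0.203 to 0.00618, and for glioma drivers from -0.0470 to 0.000558 and from -0.0426 to 0.00657. For erythroid cells they ranged from -0.246 to 0.0247 and from -0.246 to 0.0137. The cadherin family score was 0.0440 in the deposited values, which cover fewer symbols, and -0.135 to 0.0618 with 1 tumor left out. The correlation of the mitosis and neuron lists was -0.0144 with medians and -0.148 to 0.140 with 1 tumor left out. It ranged from -0.235 to 0.249 for astrocytes, from 0.05 to 0.446 for microglia and macrophages, from 0.262 to 0.742 for endothelium (highest without tumor 1), and from 0.0395 to 0.860 for the matrix list (highest without tumor 5). Depth limits low genes most: HIST1H3C averaged 0.563 CPM in low-grade areas, near 2 counts in the shallowest library.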

Other observations

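All tests in the first 2 paragraphs, on gene families, were chosen after the values were seen, as were the tests that compare lists with glial, endothelial or erythroid lists or use library size or the matrix list as a covariate, and the use of the result without tumor 3 to weigh the third pattern (leaving out each tumor in turn was itself chosen before); the exchange of areas within tumors and the regression on the matrix list were written before. The neuroligin and neurexin genes, which encode adhesion partners across the synapse, had a family mean that was higher in high-grade areas in 12 of 12 tumors, by 0.53 ± 0.42 on the log2 scale (SD; exact sign-flip permutation p = 0.000488, adjusted over 8 families 0.00195). All 7 tested members were positive, including NLGN3 (0.54 ± 0.19, SE) and NRXN2 (0.51 ± 0.19), and the mean without the called NLGN1 and NLGN4X was 0.42 (p = 0.00830). The DLX homeobox genes of interneuron development moved together as well. Of these, DLX1, DLX2, DLX5 and DLX6 also belong to the fixed list of GABAergic interneurons. That list did not pass (mean change 0.38, sign-flip adjusted p = 0.259), with 8 of its 12 measured members positive and 4 negative. DLX1 (1.03 ± 0.25, from 62.1 to 105 CPM), DLX2 (1.14 ± 0.23), DLX5 (1.10 ± 0.29), DLX6 (1.16 ± 0.38) and the long non-coding DLX6-AS1 (1.38 ± 0.49, from 1241 to 2848 CPM) were all positive, with a family mean of 1.08 ± 1.25, higher in 10 of 12 tumors (p = 0.0156, adjusted 0.0312), which missed the threshold when any of tumors 1, 2, 3, 4, 9 or 11 was left out (0.95, adjusted 0.0625, without tumor 3). Among 15 AMPA receptor genes and their auxiliary subunits, GRIA4 (0.93 ± 0.18), CACNG5 (0.99 ± 0.20), CACNG4 (0.89 ± 0.24) and CACNG7 (0.57 ± 0.13) were higher when adjusted over the family alone. The family as a whole did not pass (0.23 ± 0.59, higher in 6 of 12 tumors, adjusted p = 0.353) except in the authors' deposited values (0.36, adjusted p = 0.0117). Those values cover fewer symbols, so fewer members may have been scored there.

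The mean of the 5 tested HOX genes fell in 12 of 12 tumors, with a change of -1.21 ± 0.91 (p = 0.000488, adjusted 0.00195). Besides HOXB4, HOXB2 went from 4.69 to 1.70 CPM (-1.58 ± 0.41) and HOXB3 from 8.64 to 3.24 CPM (-1.24 ± 0.28), and HOXC4 (-1.17 ± 0.46) was lower in 9 of 12 tumors. HOXA2 (-0.83 ± 0.45) did not pass even when adjusted over the family alone (edgeR adjusted p = 0.0796), and the mean without HOXB4 was -1.17 (p = 0.000977). Leukocyte immunoglobulin-like receptors, scored together with LAIR1, a receptor outside that family, were all negative (10 of 10 genes). Their mean was -0.53 ± 0.44, lower in 11 of 12 tumors (exact sign-flip p = 0.000977, adjusted 0.00260). LILRB5 was at -1.08 ± 0.35 and LAIR1 at -0.52 ± 0.10. Genes linked to fetal growth were split. The RNA-binding proteins LIN28A (1.12 ± 0.21, from 5.52 to 12.2 CPM) and IGF2BP2 (0.57 ± 0.16) were higher and IGF2 (-1.44 ± 0.49, from 3082 to 1323 CPM, lower in 11 of 12 tumors) and IGF2BP1 (-1.06 ± 0.41) were lower when adjusted over the family alone, with a mean of 0.13 ± 0.49 that did not pass (adjusted p = 0.493) except with the median over members (0.36, adjusted p = 0.0289). Cadherins (-0.03 ± 0.57, adjusted p = 0.849) and potassium channels (-0.17 ± 0.76, adjusted p = 0.515) did not pass as families.

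Exchanging the areas within tumors gave a measure of chance. Among 60 such splits, the real one included, 1 gave as many genes higher as the real 14 and 1 gave as many lower as the real 15, namely the real split. The highest count in the other splits was 0. The real counts thus stood apart from the splits run (p = 0.0167 in this split test). That is the smallest p that 60 splits allow, so chance is made less likely but is not excluded. A split and its mirror are one, so each split was counted by the larger of its directions. For lists called by camera, 28 of 60 splits then gave as many as the real 10 lower, the larger direction of the real split. For the real 9 higher it was 33 of 60, which sets the smaller real direction against the larger of each other split. Another split had up to 19 lists in 1 direction, so chance cannot be excluded for the camera counts.

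The first pattern is the rise of S phase histone genes and the higher values of mitosis genes in high-grade areas. The list of G1/S and DNA replication did not pass (0.12, exact sign-flip adjusted p = 0.539). In tumor 3, whose low-grade library was the shallowest, the lists parted. Histones were at 2.04 there, mitosis at -0.58 and G1/S at -0.93. A larger share of tumor cells would raise glial genes alike if tumor cells of both areas express them equally. The histone list exceeded the mean of 3 glial lists by 0.71 per tumor (exact sign-flip p = 0.0112). Whether the tumor cells of both areas express glial genes equally was not tested, so this excess cannot decide about the tumor cell share. For the mitosis list the excess of 0.37 did not pass (p = 0.145), so a larger tumor cell share cannot be told apart from more dividing cells there. With library size as a covariate, the mean change of the mitosis list was 0.52 against 0.48 without it. Depth did not differ detectably between the areas, so the covariate could hardly move this mean, and the test decides little about depth. More cells in cycle is a candidate explanation that stays open, and since areas were picked by appearance it may be part of how they were chosen.

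The second pattern is the fall of immune genes, taken as the mean of the macrophage, MHC class II and T cell lists (-0.56, lower in 12 of 12 tumors). If it came from less desmoplastic stroma, a tumor with an unchanged matrix list would show no fall, but the regression gave -0.37 at that point (95% bootstrap interval -0.56 to -0.19). A larger share of tumor cells could lower the genes of all other cells. The immune lists fell by more than the endothelial list, with a mean difference of -0.46 (exact sign-flip p = 0.000488, 12 of 12 tumors). Among stromal lists, fibroblasts (-0.85) and matrix (-0.57) fell on average by as much or more, and pericytes (-0.23) and basement membrane (-0.20) by less. The endothelial list alone thus cannot decide whether a larger tumor cell share lowered the immune genes. Less blood cannot be told apart, because the difference from the erythroid list, -0.40, was negative in 10 of 12 tumors but did not pass (exact sign-flip p = 0.0518). Tumor 3, with the shallowest low-grade library, went the other way, at -2.04 for the erythroid list and -1.30 for the immune lists. So did tumor 10, at -0.84 and -0.20. With the matrix list as a covariate, the mean change of T cell genes was -0.44 and that of macrophage genes -0.26. Without it they were -0.75 and -0.38, so stroma may account for part of the fall. Fewer or less active immune cells in high-grade areas remains a hypothesis.

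The third pattern did not pass its test after adjustment: mitochondrially encoded transcripts had a mean change of -0.60 in high-grade areas (adjusted p = 0.0706). The shallow low-grade library of tumor 3, at -4.60, could be its source, but without it the mean change was -0.24, lower in 8 of 11 tumors (exact sign-flip p = 0.0420, adjusted over the lists 0.111). That library therefore sets much of the size, and the change without it kept its sign but did not pass after adjustment, while with it the list passed without tumor 6 or 7 (adjusted p = 0.0452 and 0.0470). RNA quality and cell content of the areas stay open, as neither was tested for these genes, and no biological explanation was tested.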
